A study of Mus musculus with 12 samples.

How the data were processed

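The series holds 12 RNA-seq libraries of NIH-3T3 cells, an immortalised mouse embryonic fibroblast line. Of these, 3 come from cells with intact Crls1 (WT) and 3 from each of 3 lines called KO1, KO2 and KO3. Per the labels' protocols, cells were transfected with a plasmid carrying Cas9 and a guide RNA against Crls1, sorted individually on GFP fluorescence and grown into lines, and the loss of Crls1 alleles was checked by sequencing genomic DNA. All samples were grown in 1 medium with glucose, pyruvate and uridine, per the labels. The labels do not say whether the WT cells went through the same sorting, where in the gene the guide cuts, or whether the 3 libraries of a line came from separate cultures. All p-values below therefore measure only the spread between these samples, which may be technical replicates. Per the labels' protocols, total RNA was depleted of cytoplasmic ribosomal RNA and primed with random hexamers. Mitochondrial transcripts and RNAs without a poly(A) tail therefore enter the libraries.

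Per the submitters' processing notes, cutadapt, Salmon 0.14.1 and DESeq2 1.24.0 were used with the mouse build GRCm38 (mm10). The role, order and settings of these tools are not given in the sources used here, nor is the strandedness of the counting. The authors deposited a table of normalized read counts, used here as a signal that is never negative, with 54392 gene rows and 1 column per library. Each library has its own smallest step, and 99.95% to 99.99% of its values are whole multiples of that step within 0.02. The deposited values are thus whole numbers per gene divided by 1 size factor per library, and multiplying back gave 32929242 to 42211807 reads per library. Salmon gives estimated counts, so these reads may be estimates rounded to whole numbers, and the zeros, bounds and counting intervals below then rest on rounded estimates. The authors also deposited, for each clone against WT, a table of log2 fold changes with standard errors and a table of p-values with adjusted p-values, per the file headers from DESeq2. All but 35 of the 54392 gene identifiers matched GENCODE release M21, from which symbols and GRCm38 coordinates were taken. No column of another sample was present (0 unused columns).

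Genes with a normalized count of at least 10 in at least 3 of the 12 libraries were tested, which left 15073 genes, while 27258 were at 0 in every library. A gene silent in WT passed this filter only through the clones, so its rise was in part fixed by the filter. The reverse holds for a gene silent in the clones. Fold changes are differences of log2(value + 1) and understate the change of weakly expressed genes. Limma 3.58.1 in R 4.3.3 with a trended prior variance was fitted to all 4 groups together (8 residual degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes. The 42 gene lists cover mitochondrial RNAs and proteins, cardiolipin and phospholipid synthesis, lipid and energy metabolism, stress responses, growth, inflammation, matrix and markers of 8 cell types. Of these, 40 had the minimum of 3 tested members. Counts of list members are given over all genes tested and adjusted over the list alone.

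Groups, tests, lists, the alternatives listed as planned and the rule for naming genes were fixed before the data were examined. The rule takes Crls1, and for changes shared by all 3 clones the 12 genes that rose and the 12 that fell with the largest smallest-of-3 fold change and a mean of at least 100. For each clone it takes the 5 up and 5 down with the largest fold change, a mean of at least 100 over that clone and WT and no overlap of the clone's libraries with WT, and the 3 up and 3 down among genes that also differ from both other clones in the same direction. Predicted gene models are left out of these. From each gene list described, up to 4 members with the smallest adjusted p are named (over all clones, the smallest largest-of-3 adjusted p), and all mitochondrial RNAs and cardiolipin pathway genes may be named. Some genes that the rule takes are not reported here. Rpph1, Rmrp and Lars2 are named by this rule, and the strong spread of their WT libraries was noticed afterwards.

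Where a group held 0 reads, a fold is given as a lower bound against a floor of 3 reads over the group, and where it held 1 to 3 reads, the ratio is given with its 95% exact counting interval. Such bounds and intervals cover counting error only. Protein-coding mitochondrial genes were compared with their nuclear copies by shared 31-nucleotide stretches, and a copy on chromosome 1 was added to its mitochondrial gene in a second version of the values. The alternatives tried were pseudocounts of 0.5 and 5, no filter or a filter at 50, upper-quartile and quantile normalization, an untrended prior, fits of only the groups compared, the replicate number as a block, leaving out each library, camera on ranks, the estimated correlation and the authors' DESeq2 tables. After the data were seen, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, the summed nuclear copies, removal of a loess trend on GC content and transcript length, and subtraction of the median of 51 neighbouring genes were added.

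The procedures were tested on simulated data. For KO1 against WT (14702 genes), limma recovered 74.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, and called 9 unchanged genes. In 15073 simulated genes of the same comparison, edgeR recovered 74.6%, 98.5% and 100% with 8 unchanged genes called, and DESeq2 85.1%, 98.5% and 100% with 30. Only 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold, a far smaller share than the 52.3% called in KO1. They were drawn from genes with a mean of at least 100, so the rates do not describe weakly expressed genes. A list shifted by -0.5 in simulated KO2 (14712 genes) was called with both correlations, with a median of -0.52 and 0 other lists called. Genes were simulated independently of each other, so this does not show how camera acts on correlated genes. In the data the estimated correlation was 0.31 for cholesterol synthesis and 0.677 for complex I subunits. A simulated region shift of 0.5 in KO3 (14705 genes) had a median of 0.50 before and 0.01 after subtraction of the neighbours' median. A GC slope of 2 put into KO3 (14709 genes) was measured as 2.03 before and 0.06 after the loess correction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.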

Results

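Gene expression was measured by total RNA sequencing in NIH-3T3 cells, an immortalised line of mouse embryonic fibroblasts, with 3 libraries each of WT cells and of the Crls1-targeted lines KO1, KO2 and KO3. Crls1 encodes cardiolipin synthase, the enzyme that makes cardiolipin, a phospholipid of the inner mitochondrial membrane. The series title places the work in the study of how cardiolipin bears on mitochondrial ribosomes at that membrane. Depth ranged from 32929242 reads in WT replicate 1 to 42211807 in KO3 replicate 2. Mitochondrial messenger RNAs and their nuclear copies took 6.02% to 7.07% of the reads. Across the genes tested, log2 values correlated at r = 0.982 to 0.990 within a group, 0.918 to 0.941 between WT and a clone and 0.942 to 0.951 between clones (genes are not independent replicates). WT replicate 1 stood apart from the other WT libraries, with a chi-square per degree of freedom of 53.3 and 56.5 against them, while those differed from each other by 17.5. Pairs within a clone gave 4.68 to 25.7, so no pair of libraries was within sampling noise. All p-values rest on the spread between libraries that may be technical replicates, and each clone descends from 1 sorted cell.

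Crls1 RNA was lower in every clone library than in every WT library, and lowest in KO1. The gene (ENSMUSG00000027357.16) lies on the plus strand of chromosome 2 at 132846666 to 132866785 (GRCm38) and has 5 annotated transcripts, of which the longest, Crls1-201, has 7 exons. Its mean was 815 ± 68.4 normalized counts in WT, 210 ± 2.67 in KO1, 349 ± 21.1 in KO2 and 381 ± 23.9 in KO3 (SD, n = 3 each). By limma, Crls1 fell by 1.95 on the log2 scale in KO1 (SE 0.09, adjusted p = 2.99e-09), by 1.22 in KO2 (adjusted p = 1.61e-07) and by 1.09 in KO3 (adjusted p = 4.54e-07). KO2 and KO3 kept more Crls1 RNA than KO1, by 0.73 (adjusted p = 3.18e-05) and 0.85 (adjusted p = 8.74e-06), and KO3 minus KO2 was 0.12 (adjusted p = 0.253). The authors' deposited table gives log2 fold changes of -1.95, -1.21 and -1.09 for Crls1. The counts cover the whole gene and the guide's position is not given in the sources used here, so they do not show whether the remaining RNA encodes the enzyme.

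**Figure D1:**
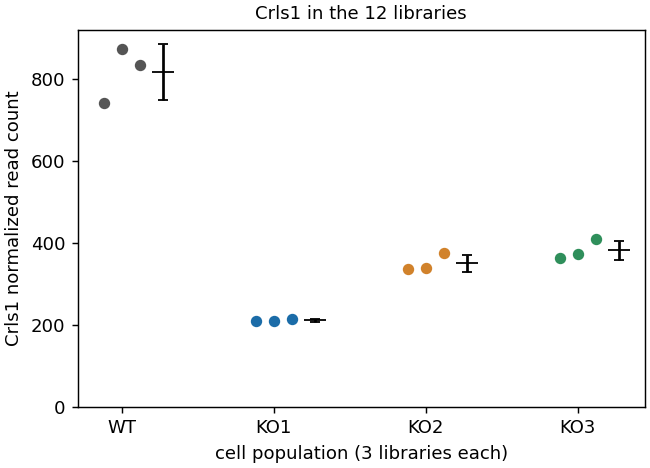
Normalized read counts of Crls1 (y axis, linear from 0) in each of the 3 libraries of WT, KO1, KO2 and KO3 (points), with the group mean and SD. The WT libraries lie between 740 and 873 and the clone libraries between 209 and 408.

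Among 15 tested genes of the cardiolipin pathway, a list that leaves out Crls1 itself, 3 rose and 3 fell in KO1, 6 rose and 4 fell in KO2, and 3 rose and 4 fell in KO3, with the same counts adjusted over the list alone. Lclat1, an acyltransferase that remodels lysocardiolipin, fell in every clone (-0.56, -0.64 and -0.75 in KO1, KO2 and KO3). Taz, which encodes the transacylase tafazzin, rose in all of them (0.40, 0.67 and 0.52). Pla2g6, a phospholipase, rose in KO2 (0.61) and KO3 (0.46). Prelid1, which carries phosphatidic acid between the mitochondrial membranes, fell in KO3 (-0.62). Its difference in KO2 was -0.55, a call that was lost without WT replicate 2 (adjusted p = 0.0583), WT replicate 3 (0.0619) or KO2 replicate 3 (0.0623). With the median of neighbouring genes subtracted, Prelid1 was at -0.12 in KO2 and -0.22 in KO3, both uncalled. Ptpmt1, the phosphatase that makes phosphatidylglycerol, differed by 0.58 in KO3, but by 0.30 without WT replicate 1 (adjusted p = 0.0798), and the call was also lost on leaving out any 1 KO3 library or subtracting the neighbours' median (0.43, adjusted p = 0.0667). In KO2 Ptpmt1 was at -0.45 and not called by limma (adjusted p = 0.0709), but was called by the authors' table (-0.47, adjusted p = 0.0344), by edgeR (-0.50, 0.0459), by DESeq2 (-0.51, 0.0260), with quantile normalization (-0.66, 0.0113) and with the neighbours' median subtracted (-0.58, 0.0160). Without WT replicate 1 it was called at -0.74 in KO2 (adjusted p = 4.69e-04) and at -0.47 in KO1 (0.0111), where it was at -0.19 with all libraries (0.458). Leaving out that library also gave calls of Prelid1 in KO1 (-0.55) and of Tamm41 in KO1 (-0.38) and KO3 (-0.37). As a group the pathway did not pass limma's camera test (adjusted p = 0.686, 0.719 and 0.795).

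The lists called by camera at the preset correlation in all 3 clones were cholesterol synthesis, cell cycle and contractile or YAP target genes. Regroupings that mix libraries of WT and a clone also gave as many called lists for KO1 and KO2, as set out below. Of 23 cholesterol synthesis genes, 21 fell and 0 rose in KO1, 21 fell and 1 rose in KO2, and 22 fell and 0 rose in KO3, and 20 fell in every clone. Adjusted over the list alone, 22 fell and 1 rose in KO1, 21 fell and 1 rose in KO2, and 22 fell and 0 rose in KO3. Hmgcs1, an early enzyme of the pathway, went from 11580 ± 983 normalized counts in WT to 5707 ± 109 in KO1, 4364 ± 261 in KO2 and 4164 ± 133 in KO3 (SD, n = 3). Idi1, the isopentenyl diphosphate isomerase, fell by 1.49, 2.02 and 1.81 on the log2 scale in KO1, KO2 and KO3 (SE 0.08). Insig1, a sterol-regulated protein that holds back the SREBP pathway, fell by 0.79, 1.51 and 1.44 (SE 0.04). The list medians were -0.65, -1.07 and -1.02 (camera adjusted p = 4.67e-09, 2.38e-09 and 2.16e-12). With an estimated correlation between genes none of the 3 calls held (adjusted p = 0.397, 0.229 and 0.224 with an estimated correlation). Limma's fry test, which asks only whether the genes move on balance one way, gave adjusted p = 1.65e-06, 1.04e-07 and 5.49e-08, but it also called most lists, 29, 27 and 30 of 40 in KO1, KO2 and KO3.

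Genes of DNA replication and mitosis fell as a group in each clone, most in KO2. Of 39 cell cycle genes, 22 fell and 3 rose in KO1, 38 fell and 0 rose in KO2, and 21 fell and 6 rose in KO3, with the same counts adjusted over the list alone. The replication clamp Pcna fell by 0.86, 1.05 and 0.93 on the log2 scale in KO1, KO2 and KO3 (SE 0.07), and Mcm6, a subunit of the replicative helicase, changed by -1.02, -1.42 and -0.97 (SE 0.08). In KO2 the cyclins Ccna2 (-1.14) and Ccnb1 (-0.94) fell as well. Medians were -0.27, -0.77 and -0.28 (camera adjusted p = 5.59e-04, 1.23e-12 and 0.0152; adjusted p = 0.560, 0.280 and 0.685 with an estimated correlation). In the test between clones, the median of the gene-by-gene differences, KO2 minus KO1, was -0.48 (camera adjusted p = 1.48e-09; adjusted p = 0.593 with an estimated correlation).

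Contractile and YAP target genes fell in number too. Of 20 genes, 13 fell and 2 rose in KO1 (14 and 2 adjusted over the list alone), 15 fell and 3 rose in KO2, and 14 fell and 3 rose in KO3 (unchanged adjusted over the list alone). Ccn2, a secreted matrix protein and YAP target, fell by 1.13, 2.33 and 2.25 on the log2 scale in KO1, KO2 and KO3 (SE 0.10), and the tropomyosin Tpm4 by 0.56, 1.10 and 0.85 (SE 0.04). Smooth muscle actin Acta2 fell by 3.09 in KO2 (SE 0.07) and Tagln, an actin-binding protein of smooth muscle, changed by -3.47 in KO3 (SE 0.14). Medians were -0.30, -0.49 and -0.42 (camera adjusted p = 7.38e-03, 1.15e-04 and 1.71e-03; adjusted p = 0.397, 0.178 and 0.224 with an estimated correlation). The KO1 call was lost with quantile normalization (median -0.22, adjusted p = 0.0519).

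Of the fatty acid lists, 17 of 22 oxidation genes rose and 0 fell in KO2 (18 and 0 adjusted over the list alone), and 12 rose and 3 fell in KO3 (the same adjusted over the list alone). Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose by 1.14, 1.31 and 0.98 in KO1, KO2 and KO3 (SE 0.07), and the thiolase Acaa2 by 1.04, 1.38 and 1.12 (SE 0.11). The list medians were 0.35 in KO2 and 0.36 in KO3 (camera adjusted p = 1.75e-04 and 0.0278; adjusted p = 0.178 and 0.308 with an estimated correlation). Of 17 fatty acid synthesis genes, 12 fell and 2 rose in KO2, and 10 fell and 1 rose in KO3, with the same counts adjusted over the list alone. The elongase Elovl6 fell by 1.44, 1.69 and 1.64 in KO1, KO2 and KO3 (SE 0.11) and the desaturase Fads1 by 0.75, 0.87 and 0.59. Medians were -0.48 in KO2 and -0.39 in KO3 (camera adjusted p = 3.12e-03 and 9.42e-03; adjusted p = 0.297 and 0.338 with an estimated correlation). In KO1, 7 oxidation genes rose and 3 fell, 2 synthesis genes rose and 8 fell, and neither list passed the test (camera adjusted p = 0.234 and 0.0782).

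Over the list results of KO1, KO2 and KO3, the median, the mean and the direction of the test differed in sign in 0 of 27 called and in 13 of 93 uncalled results.

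**Figure D2:**
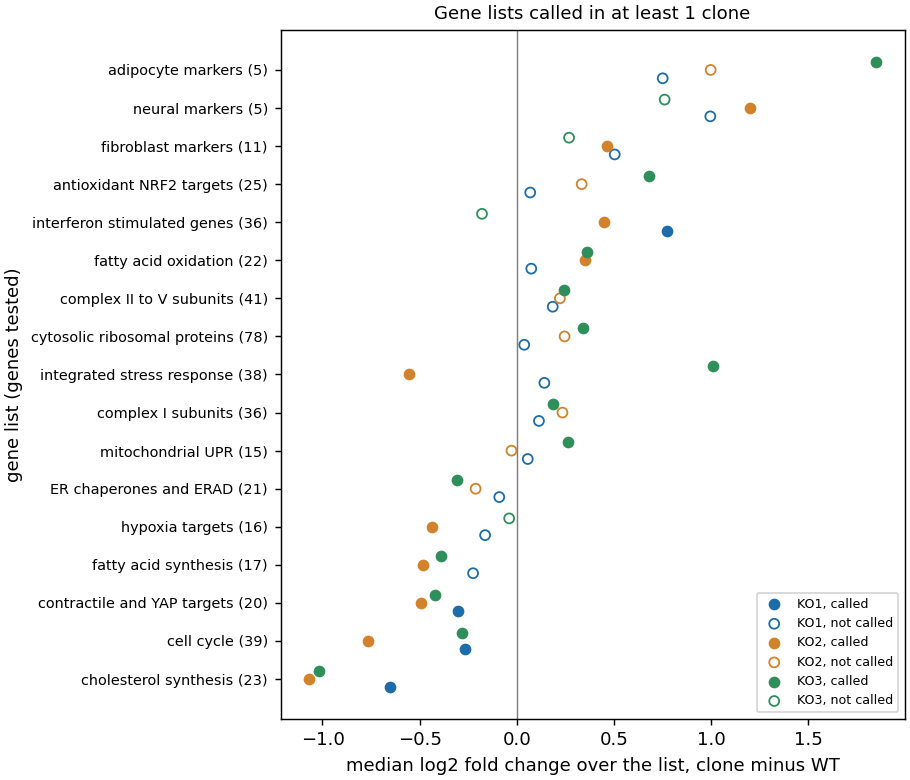
Median log2 fold change against WT (x axis) of the gene lists called in at least 1 clone, with KO1, KO2 and KO3 as separate markers, filled where the list passed the camera test with the preset correlation. Cholesterol synthesis lies between -1.07 and -0.65 in all 3 clones, and the integrated stress response lies at 1.01 in KO3 and -0.56 in KO2.

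Single genes that changed alike in all 3 clones included adhesion, matrix and signalling genes that went from near silence to high expression or the reverse. Tnr, which encodes the matrix glycoprotein tenascin-R (chromosome 1, 159523769 to 159931729), rose from 18.7 ± 6.07 normalized counts in WT to 2016 ± 172 in KO1, 1484 ± 127 in KO2 and 1572 ± 102 in KO3 (SD, n = 3). Cd34, a surface sialomucin, rose by 5.09, 5.90 and 4.64 on the log2 scale, and Hgf, the hepatocyte growth factor, by 6.11, 6.69 and 4.69. Sdk1, a cell adhesion molecule, had 0 reads in WT and was at least 422-fold higher in KO1, 61.7-fold in KO2 and 51.2-fold in KO3, with the floor of 3 reads over the group. Enpp5 (chromosome 17, 44078813 to 44086567), a member of the nucleotide pyrophosphatase family, fell from 1595 ± 117 in WT to 3.88 in KO1, 3.30 in KO2 and 1.17 in KO3. Cyp1b1, a cytochrome P450, had log2 fold changes of -6.13, -5.86 and -6.28, and the phospholipase Plce1 of -9.17, -7.65 and -8.94. Tnfsf18, a TNF family ligand, changed by -8.13 in KO1 and -8.06 in KO3 and had 0 reads in KO2, which is at least 616-fold lower. The other genes named by the same rule were Thsd7a, Itgbl1, Aldh3a1, 9930111J21Rik2, Pappa, Hecw2, Dclk1 and Itgb8, which rose by 4.50 to 7.63, and Abi3bp, Trim54, P2ry14, Il2rg, Rgs16, Agap2, Hdac9 and Selp, with log2 fold changes of -9.05 to -4.34.

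In all, 1945 genes rose and 2008 fell in every clone, of 15073 tested (553 and 412 by at least 2-fold in each). Calls were made for 4503 genes in all 3 clones, for 3695 in 1 clone only, and 1263 genes had opposite calls in different clones. Independent lists of the same sizes would share 324 genes that rose and 319 that fell. In 100 simulations of all 4 groups, WT included, without change and with each gene's own spread, 0 genes were shared. That outcome follows from simulating no change, so it lends no support to the shared genes. Fold changes correlated across genes at r = 0.629 between KO1 and KO2, 0.671 between KO1 and KO3 and 0.628 between KO2 and KO3. The values were 0.498, 0.503 and 0.496 for simulated unchanged groups that share a simulated WT group. The covariances were 0.849, 0.973 and 0.828 against 0.0396, 0.0401 and 0.0394 in the simulation. KO1 and KO2 shared 2775 genes that rose and 2820 that fell (1211 and 1168 for independent lists), KO1 and KO3 shared 2493 and 2488 (1084 and 1045), and KO2 and KO3 shared 2506 and 2579 (1207 and 1255). The 3 WT libraries cannot be divided into parts of at least 2, so their shared noise was judged by the simulation alone. At the simulated spread, that noise gave covariances far below those observed. A trait of the WT line itself would enter all 3 comparisons alike, and dividing the WT libraries could not show it. Part of the excess may come from the shared controls in this way.

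**Figure D3:**
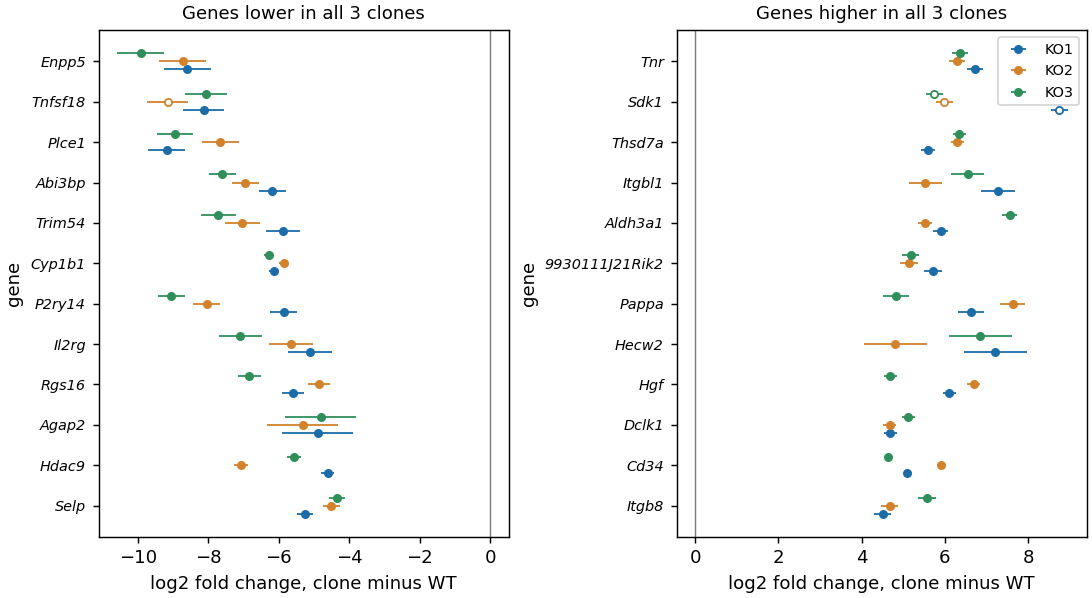
Log2 fold change against WT (x axis, log2 of the normalized count + 1) of the 12 genes that rose and the 12 that fell most in all 3 clones, with KO1, KO2 and KO3 as separate markers and the SE as bars, and open markers where a group held at most 3 reads. Enpp5 lies at -8.59, -8.73 and -9.91 and Tnr at 6.73, 6.28 and 6.37.

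KO1 differed from WT in single genes with large changes and in interferon-stimulated genes, besides the groups described for all clones. Slit2, a secreted axon guidance protein (chromosome 5, 47983138 to 48307733), had 0 reads in WT and 5103 in KO1, at least 1720-fold more, and Myf5, a myogenic transcription factor, was at least 1340-fold higher. Both also differed from KO2 and KO3, where Slit2 had 0 and 2 reads and Myf5 0 and 1. Ptprt, a receptor tyrosine phosphatase, had 1 read in WT and 2435 in KO1, a ratio of 2460 (95% counting interval 440 to 97000). Ces1g, a carboxylesterase, was at least 410-fold higher. Grpr, a receptor for gastrin-releasing peptide, went from 1128 reads to 2 (ratio 559, interval 154 to 4620), Lrch2 had 0 reads in KO1 (at least 283-fold lower), and Tnfrsf11b, the decoy receptor osteoprotegerin, fell by 7.12 on the log2 scale. Slc6a4, the serotonin transporter, fell by 5.92. Several of these changes were shared with other clones. Lrch2 also had 0 reads in KO2 and KO3 (at least 317-fold and 297-fold lower), and Ces1g was at least 93.8-fold higher in KO3. Grpr, Tnfrsf11b and Slc6a4 were below WT in every KO2 and KO3 library as well.

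Of 36 interferon-stimulated genes, 23 rose and 5 fell in KO1, with the same counts adjusted over the list alone. Gbp2, an interferon-induced GTPase, rose by 0.90 (SE 0.07), Gbp7 by 2.35 (SE 0.26) and Ddx58, the RNA sensor RIG-I, by 0.78, whereas the class I antigen gene H2-K1 fell by 4.70 (SE 0.28). The list median was 0.77 (camera adjusted p = 2.15e-03; adjusted p = 0.0935 with an estimated correlation). In the integrated stress response list, 17 of 38 genes rose and 6 fell (18 and 6 adjusted over the list alone), among the former Ddit3 by 1.10 and Trib3 by 1.50, but the list did not pass the test (median 0.14, camera adjusted p = 0.0782). It was called without KO1 replicate 3 (adjusted p = 0.0423), with no filter on low values (0.0155), with quantile normalization (median 0.21, 0.00514) and with the neighbours' median subtracted (0.0396). Over all genes, 4049 rose and 3829 fell in KO1 (52.3% of 15073, with 1554 and 714 changed by at least 2-fold). In addition to the calls described for all clones, the interferon list was the only other of 40 lists called in KO1.

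KO2 showed lower stress response genes and higher fatty acid oxidation and interferon genes. Of 38 integrated stress response genes, which ATF4 and its partners induce, 29 fell and 5 rose, with the same counts adjusted over the list alone. Cth, an enzyme of cysteine synthesis, fell from 487 to 132 normalized counts (-1.89, SE 0.11), and Gpt2, a mitochondrial alanine transaminase, fell by 0.77, while the receptor Vldlr rose by 1.23. The list median was -0.56 (camera adjusted p = 4.62e-05; adjusted p = 0.297 with an estimated correlation). Of 36 interferon-stimulated genes, 19 rose and 4 fell (the same adjusted over the list alone), among them Trim30a, which rose by 1.91, and Ifit3b, which rose by 4.64. The interferon median was 0.45 (camera adjusted p = 0.0153; adjusted p = 0.178 with an estimated correlation).

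Other lists called in KO2 lay closer to the threshold. Of 16 hypoxia targets, 11 fell and 2 rose, with P4ha2, a subunit of collagen prolyl hydroxylase, at -0.72 and the stress-induced gene Ndrg1 at 2.44 (median -0.44, camera adjusted p = 0.0373; adjusted p = 0.178 with an estimated correlation). This call was lost with the GC and length trend removed (adjusted p = 0.0527) and with the neighbours' median subtracted (0.0710). Of 11 fibroblast markers, 6 rose and 2 fell, with the growth factor receptor Pdgfra at 1.85 and the stem cell antigen Ly6a at 2.23 (median 0.46, camera adjusted p = 0.0300; adjusted p = 0.178 with an estimated correlation). The fibroblast call was lost with the GC and length trend removed (median 0.29, adjusted p = 0.0527), with camera on ranks (0.0670) and with only KO2 and WT in the fit (0.0566). Of 12 neural markers, 5 passed the filter on low values. All 5 rose, including Tubb3, a neuronal tubulin, by 2.74 (median 1.20, camera adjusted p = 0.0484; adjusted p = 0.232 with an estimated correlation). Gfap, an astrocyte filament protein, went from 1 read to 102, a ratio of 91.7 (interval 16.1 to 3660). A marker this low in WT passed the filter only through the clones, so its rise, and the neural call in part, were built in. The neural call was lost without WT replicate 1 (adjusted p = 0.0510), KO1 replicate 2 (0.0513), KO1 replicate 3 (0.0513) or KO2 replicate 1 (0.0551), and under further settings. These 3 lists gave the same counts adjusted over the list alone. The fibroblast and neural lists were not called as different between KO2 and KO1 (camera adjusted p = 0.152 and 0.472) or KO3 and KO2 (0.187 and 0.489). Fibroblast markers gave 7 that rose and 3 that fell in KO1 and 6 and 1 in KO3, and neural markers 3 and 0 in KO1 and 4 and 0 in KO3, also adjusted over the list alone. The fibroblast list was called with no filter in KO1 (adjusted p = 0.0155) and KO3 (0.0106) and with quantile normalization in KO1 (0.0193). Subtraction of the neighbours' median gave fibroblast calls in KO1 (0.0148) and KO3 (0.0378) and a neural call in KO3 (0.0451).

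The single genes that moved most in KO2 included Tram1 (chromosome 1, 13564698 to 13589910), which encodes a membrane protein of the translocon and went from 4125 reads in WT to 1 in KO2, a ratio of 4590 (interval 823 to 181000). Ptgr2, a prostaglandin reductase, went from 1306 reads to 1 (ratio 1450, interval 260 to 57400), and the lipid transporter Abca3 to 0 (at least 379-fold lower). Il1rl2, an interleukin receptor, fell by 7.13 on the log2 scale. Upwards, Cldn19, a tight junction protein, had 2 WT reads and 1559 in KO2 (ratio 701, interval 194 to 5790), Sox1ot, a noncoding transcript, 1 and 1696 (ratio 1520, interval 273 to 60200) and Pcnx2 3 and 1114 (ratio 334, interval 114 to 1620). Pappa, a protease of IGF-binding proteins, rose by 7.63 and Tie1, an endothelial receptor, by 7.29. Tram1, Ptgr2, Il1rl2, Cldn19, Pcnx2 and Pappa also differed from both other clones. Several of these genes still changed elsewhere in the same direction. Ptgr2 was at 2.14, 1.06 and 6.89 normalized counts in the KO1 libraries, and Abca3 had 0 reads in KO3 (at least 354-fold lower). In KO1, Sox1ot had 1539 reads (ratio 1550, interval 278 to 61300), Cldn19 172 (ratio 86.7, 23.6 to 722) and Pcnx2 204 (ratio 68.6, 23.1 to 335). Over all genes, 4507 rose and 4598 fell in KO2 (60.4%, with 1534 and 1147 changed by at least 2-fold), and 10 of the 40 lists were called.

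KO3 showed higher expression of stress response and antioxidant genes. Of 38 integrated stress response genes, 36 rose and 0 fell, also adjusted over the list alone. Trib3, a pseudokinase induced by ATF4, went from 665 normalized counts in WT to 6900 in KO3 (3.39, SE 0.10), and the transcription factor Ddit3 from 561 to 4399 (2.98, SE 0.09). The list median was 1.01 (camera adjusted p = 4.57e-15; adjusted p = 0.224 with an estimated correlation). Of 25 NRF2 target genes, which act against oxidants, 20 rose and 1 fell (the same adjusted over the list alone), with the quinone reductase Nqo1 at 2.13 (SE 0.06) and the glutathione transferase Gsta1 at 3.93 (SE 0.15). The NRF2 median was 0.68 (camera adjusted p = 4.02e-07; adjusted p = 0.248 with an estimated correlation). Of 21 endoplasmic reticulum chaperones and degradation factors, 13 fell and 4 rose (14 and 4 adjusted over the list alone), with the disulfide isomerases Pdia6 at -1.71 and Pdia3 at -1.20 (median -0.31, camera adjusted p = 9.42e-03; adjusted p = 0.224 with an estimated correlation). The chaperone list was similar in KO2, where 14 fell and 4 rose (median -0.21, camera adjusted p = 0.0700; called with no filter, 0.0171, with the neighbours' median subtracted, 0.0181, and without WT replicate 1, 0.0414), and KO3 minus KO2 was not called (0.340). In KO1, 8 fell and 3 rose (median -0.09, camera adjusted p = 0.252), with the same counts adjusted over the list alone in both clones. NRF2 targets gave 10 that rose and 4 that fell in KO1 and 13 and 5 in KO2 (camera adjusted p = 0.258 and 0.0588; 10 and 4, and 14 and 6, adjusted over the list alone).

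Of the lists of nuclear genes for mitochondrial proteins, the respiratory complex and unfolded protein response lists were called in KO3, and each call was lost without WT replicate 1, the library that stood apart. The respiratory lists were not called as different between KO3 and KO2 (camera adjusted p = 0.653 for complex I and 0.475 for complexes II to V) or between KO3 and KO1 (0.111 and 0.0536), and in KO3 they did not pass fry (0.0715 and 0.0511). In KO1, 6 complex I subunits rose and 0 fell and 10 subunits of complexes II to V rose and 5 fell (medians 0.11 and 0.18, camera adjusted p = 0.365 and 0.378; 3 and 0, and 4 and 3, adjusted over the list alone). In KO2, 13 complex I subunits rose and 2 fell (median 0.23, camera adjusted p = 0.0709), and 16 subunits of complexes II to V rose and 3 fell (median 0.22, 0.123; 13 and 2, and 14 and 3, adjusted over the list alone). Both KO2 lists were called without WT replicate 2 (adjusted p = 0.0186 and 0.0356), WT replicate 3 (medians 0.37 and 0.31, 0.0237 and 0.0299) or KO2 replicate 3 (0.0432 and 0.0482), with no filter (0.0145 and 0.0363) and with quantile normalization (0.0383 and 0.0197), and complex I with the neighbours' median subtracted (0.0298). In KO3, of 36 complex I subunits, 12 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.0407; adjusted p = 0.765 with an estimated correlation). The median was 0.03 without WT replicate 1 (adjusted p = 0.428), 0.29 and 0.31 without WT replicates 2 and 3, 0.17 without KO3 replicate 1 (adjusted p = 0.0640) and 0.12 without KO3 replicate 3 (adjusted p = 0.0806). With the GC and length trend removed it was 0.12 (adjusted p = 0.103), and other settings also ended the call. Of 41 subunits of complexes II to V, 19 rose and 3 fell (17 and 3 adjusted over the list alone), among them Uqcr10 of complex III at 0.66 and Cox4i1 of complex IV at 0.78 (median 0.24, camera adjusted p = 0.0202; adjusted p = 0.756 with an estimated correlation). Without WT replicate 1 that median was 0.12 (adjusted p = 0.288). Of 15 genes of the mitochondrial unfolded protein response, 8 rose and 2 fell (the same adjusted over the list alone), with the protease Lonp1 at 1.52 and the chaperone Hspa9 at 1.23 (median 0.26, camera adjusted p = 0.0455; adjusted p = 0.248 with an estimated correlation). Without WT replicate 1 it was 0.17 (adjusted p = 0.112), and the call was also lost without KO1 replicate 2 (0.0511), KO2 replicate 1 (0.0513) or KO3 replicate 1 (0.0506) and with the GC and length trend removed (0.0883).

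Of 78 cytosolic ribosomal protein genes, 39 rose and 2 fell in KO3 (38 and 2 adjusted over the list alone), with Rpl23 at 0.58 and Rps3 at 0.41 (median 0.34, camera adjusted p = 3.74e-04; adjusted p = 0.685 with an estimated correlation). Without WT replicate 1 that median was 0.16 (adjusted p = 0.0135). In KO2, 23 rose and 5 fell and in KO1, 4 and 10 (camera adjusted p = 0.123 and 0.790; 11 and 5, and 0 and 9, adjusted over the list alone). Of 13 adipocyte markers, 5 passed the filter on low values, of which 3 rose and 0 fell, also adjusted over the list alone. These were Pparg, the main regulator of adipocyte formation, by 3.79, the lipase Lpl by 2.30 and the lipid droplet protein Plin4 by 1.85 (median 1.85, camera adjusted p = 9.42e-03; adjusted p = 0.248 with an estimated correlation). The same 3 genes rose in the other clones, where the list was not called (camera adjusted p = 0.0782 and 0.0698). Some alternatives called the adipocyte list there. These were the filter at 50 (adjusted p = 0.0409) and subtraction of the neighbours' median (0.0122) in KO1, quantile normalization (0.0383) in KO2, and leaving out some single libraries. Interferon-stimulated genes did not pass the test in KO3, where 8 rose and 16 fell of 36 (8 and 17 adjusted over the list alone; median -0.18, camera adjusted p = 0.248). Oas1a, an antiviral enzyme, fell by 4.98 there (SE 0.21).

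Among single genes in KO3, Mbnl3, a splicing regulator, rose from 2.17 to 2772 normalized counts (10.07 on the log2 scale), and Elmo1, an adaptor in cell migration, by 8.53. Ostn, a secreted peptide of bone and muscle, went from 1 read to 1410 (ratio 1350, interval 243 to 53500), Serpinb9d from 2 to 2596 (ratio 1250, interval 345 to 10300) and Ptprt from 1 to 2218 (ratio 2130, interval 382 to 84200). Tuba4a (chromosome 1, 75214228 to 75219865), an alpha tubulin, went from 5092 reads in WT to 1 in KO3 (ratio 5300, interval 951 to 209000). P2ry14, a receptor for UDP-sugars, fell by 9.05 and Ncan, a matrix proteoglycan, by 8.56. Mbnl3, Serpinb9d, Ostn, Tuba4a, P2ry14 and Ncan also differed from both other clones. Even so, the first 3 of these also rose in KO1. There Mbnl3 was at 545, 556 and 512 normalized counts, Serpinb9d had 352 reads (ratio 178, interval 48.8 to 1470) and Ostn 366 (ratio 369, interval 65.8 to 14600). Over all genes, 4036 rose and 4115 fell in KO3 (54.1%, with 1206 and 1208 changed by at least 2-fold), and 13 of the 40 lists were called. The authors' deposited tables call 8023, 9184 and 8246 genes in KO1, KO2 and KO3, of which 7606, 8804 and 7863 were called here in the same direction.

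Between clones, stress response and interferon genes differed. Ddit3, Trib3 and other integrated stress response genes were higher in KO3 than in KO2, with a median gene-by-gene difference of 1.32 over the 38 genes (camera adjusted p = 1.68e-22; adjusted p = 0.0590 with an estimated correlation). KO3 was also above KO1 by 0.73 (camera adjusted p = 6.92e-18; adjusted p = 0.0746 with an estimated correlation), and KO2 below KO1, with a median of -0.74 (camera adjusted p = 6.26e-14; adjusted p = 0.224 with an estimated correlation). Interferon-stimulated genes were lower in KO3 than in KO1 (median -0.61, camera adjusted p = 1.11e-06; adjusted p = 0.0101 with an estimated correlation) and than in KO2 (median -0.86, camera adjusted p = 2.72e-06; adjusted p = 0.0124 with an estimated correlation). Gbp7 rose by 2.35 in KO1 and 2.80 in KO2 against WT and fell by 2.70 in KO3. Between KO1 and KO2, 3094 genes were higher and 3601 lower in KO2, between KO1 and KO3, 3058 were higher and 3521 lower in KO3, and between KO2 and KO3, 3935 were higher and 4073 lower in KO3. Genes set apart from WT and from both other clones in the same direction numbered 770 up and 446 down in KO1, 1492 and 1681 in KO2, and 1169 and 1347 in KO3.

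The messenger RNAs encoded by mitochondrial DNA, the templates of mitochondrial ribosomes, moved by small amounts and in both directions. Nuclear copies on chromosome 1, between 24611535 and 24616197 (GRCm38), share 97.2% to 100% of their 31-nucleotide stretches with mitochondrial genes such as mt-Co2, mt-Co3 and mt-Nd3. Values of these genes alone are therefore uncertain, and values summed with the copies are given. Of 11 measured units, 1 rose and 4 fell in KO1, 0 rose and 5 fell in KO2, and 2 rose and 1 fell in KO3. As deposited, without the copies, 1 rose and 3 fell in KO1, 0 and 4 in KO2, and 2 and 1 in KO3 (1 and 2, 0 and 3, and 2 and 1 adjusted over the list alone). Mt-Nd1, a subunit of complex I, fell by 0.33 in KO1 and 0.35 in KO2 (SE 0.06), but was at -0.06 in both, and not called, with quantile normalization. Mt-Nd2 fell by 0.65 in KO2 and was at -0.09 in KO1 and -0.01 in KO3, where quantile normalization gave called differences of 0.30 and 0.37. Mt-Nd5 rose by 0.32 in KO3 and was at -0.05 in KO1 and -0.00 in KO2, where quantile normalization gave called differences of 0.40 and 0.38. Mt-Co1, a subunit of complex IV, rose by 0.32 in KO1 and 0.48 in KO3, and was called under every setting except quantile normalization. In KO2 mt-Co1 was called only by the authors' table (0.08, adjusted p = 0.0315) and DESeq2 (0.07, 0.0258). Quantile normalization gave 0 by construction, since mt-Co1 ranked 1 in every library. Mt-Nd1, mt-Nd2, mt-Nd4l_4, mt-Nd5 and mt-Cytb ranked between 6 and 22, where it also sets values largely by rank. Mt-Cytb of complex III fell by 0.40, 0.17 and 0.22 in KO1, KO2 and KO3, but with quantile normalization the differences were -0.16, 0.08 and -0.13, all uncalled. Mt-Nd6 of complex I had the largest differences among these units in KO1 and KO2, at -0.78 and -0.69 (SE 0.33), which limma did not call (adjusted p = 0.0629 and 0.0855), with 7046, 3080 and 2197 normalized counts in WT replicates 1, 2 and 3. They were called by edgeR (-0.95 and -0.84, adjusted p = 0.0296 and 0.0427), in KO1 by DESeq2 (-0.95, adjusted p = 0.0424), and without WT replicate 3 by limma (-1.14 and -1.06). Without WT replicate 1, mt-Nd6 in KO3 was called at 0.75. Mt-Atp8_6 was at -0.20 in KO3 and not called by limma (adjusted p = 0.0682), but was called by the authors' table (-0.20, adjusted p = 0.00275), DESeq2 (0.00195), edgeR (0.0190), a prior variance without a trend (0.0236), with the GC and length trend removed (0.0194) and without WT replicate 1 (-0.26, 0.00367). The calls of mt-Cytb in KO2 and of mt-Nd4l_4 as deposited in KO1 (-0.18) were lost on leaving out most single libraries, for example WT replicate 2 (adjusted p = 0.0912 and 0.0684), and that of mt-Cytb in KO3 without KO3 replicate 1 (0.0614). As a list the summed units did not pass the test in any clone (medians -0.11, -0.17 and -0.04, camera adjusted p = 0.219, 0.257 and 0.907).

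The mitochondrial ribosomal RNAs varied strongly between WT libraries. Together they took only 0.05% to 0.12% of the reads, and mt-Rnr2 ranked 98 to 509 and mt-Rnr1 209 to 2352 among genes, while mt-Co1 ranked 1. Whether the depletion of ribosomal RNA also removed part of them was not tested, so the differences below may not reflect their amounts in the cells. Mt-Rnr1, the small subunit RNA, had 13776, 3480 and 10468 normalized counts in WT replicates 1, 2 and 3, and mt-Rnr2, the large subunit RNA, fell by 0.97 in KO1 and 1.23 in KO2 (SE 0.18). In KO3 mt-Rnr2 was at -0.22 (adjusted p = 0.331), with 0.00 without WT replicate 1 (0.990) and a called -0.50 without WT replicate 2 (9.59e-04). Against WT, mt-Rnr1 rose by 1.32 in KO3 (SE 0.36) and differed by 0.09 in KO1 and 0.02 in KO2. Without WT replicate 2 the 3 differences were 0.73, -0.51 and -0.58, the last 2 called (adjusted p = 1.59e-03 and 4.88e-04). The mt-Rnr1 call in KO3 was lost with only KO3 and WT in the fit (adjusted p = 0.0567). Other noncoding RNAs showed a like spread within WT, with 239, 22.8 and 103 normalized counts of Rpph1, the RNA of ribonuclease P, and 361, 42.5 and 394 of Rmrp, the RNA of ribonuclease MRP, against 0.958 to 9.33 and 0 to 16.8 in the clone libraries. Lars2, the mitochondrial leucyl-tRNA synthetase gene, was at 12259, 7314 and 26821 in WT and 2766 to 5596 in the clones. Genes annotated as ribosomal RNA, mitochondrial ones apart, took 5.98e-04%, 9.95e-05% and 8.70e-04% of reads in WT replicates 1, 2 and 3. In the clone libraries they took 2.20e-05% to 1.09e-04%. Whether RNA depletion or library preparation differed between WT and the clones was not tested, so these differences, that of Lars2 included, may not reflect amounts in the cells.

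Proteins of the mitochondrial ribosome did not pass as a list, with 5 genes that rose and 23 that fell of 82 in KO1, 8 and 27 in KO2, and 17 and 11 in KO3 (camera adjusted p = 0.169, 0.361 and 0.385). The counts adjusted over the list alone were 3 and 19, 6 and 25, and 15 and 9. Without WT replicate 1 the ribosomal protein list was called lower in KO1, with a median of -0.21 in place of -0.09 (adjusted p = 3.17e-04), and in KO2, with -0.16 in place of -0.06 (0.00543), and with no filter in KO1 (0.0484). Mrpl16 fell by 0.58, 0.51 and 0.41 in KO1, KO2 and KO3. Of 42 mitochondrial translation factors, 5 rose and 12 fell in KO1, 9 and 13 in KO2, and 15 and 4 in KO3 (camera adjusted p = 0.385, 0.776 and 0.0678). Adjusted over the list alone, the counts were 5 and 10, 9 and 13, and 15 and 4. The KO3 list was called with no filter (adjusted p = 0.0106), with camera on ranks (0.0445) and with the neighbours' median subtracted (0.0378). The methionyl-tRNA synthetase gene Mars2 had log2 fold changes of -0.62, -0.74 and -0.76 in KO1, KO2 and KO3. None of the 22 mitochondrial transfer RNAs in the table passed the filter on low values.

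**Figure D4:**
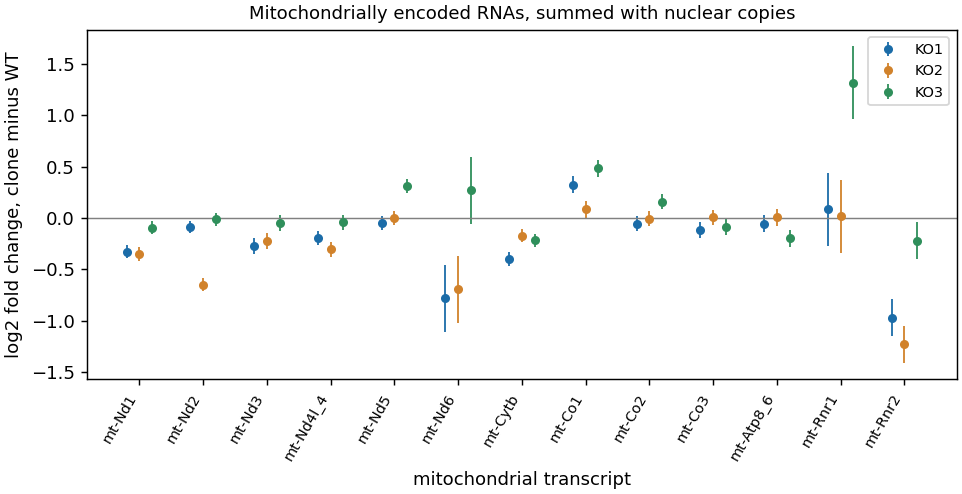
Log2 fold change against WT (y axis, normalized counts + 1, summed with nuclear copies) of the mitochondrial messenger and ribosomal RNAs in KO1, KO2 and KO3, with the SE as bars. Mt-Co1 lies at 0.32 in KO1 and 0.48 in KO3, and mt-Rnr1 in KO3 lies at 1.32.

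Fold changes of neighbouring genes moved together along the chromosomes. Medians of 213 windows of 50 consecutive expressed genes had an SD of 0.171 in KO1, 0.197 in KO2 and 0.192 in KO3, against at most 0.0777, 0.107 and 0.0852 in 200 shuffled gene orders. A window on chromosome 12, at 105784694 to 113137206, had medians of 0.25, 0.51 and 0.57 in KO1, KO2 and KO3, and one on chromosome 4, at 139352609 to 147642513, 0.44, -0.50 and 0.12 (GRCm38). On chromosome 2, the window that holds Crls1, at 132529082 to 150270300, had -0.085, 0.084 and -0.016. The window just before it, at 127436215 to 132312050, had -0.014, 0.050 and -0.217. The next one before, at 120732816 to 127298932, had -0.333, -0.174 and -0.371. Over whole chromosomes, chromosome 13 had a median of -0.26, -0.36 and -0.28 and chromosome 3 of -0.23, -0.30 and -0.26. Chromosome 10 lay at 0.34 in KO3 and chromosome X at -0.29.

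**Figure D5:**
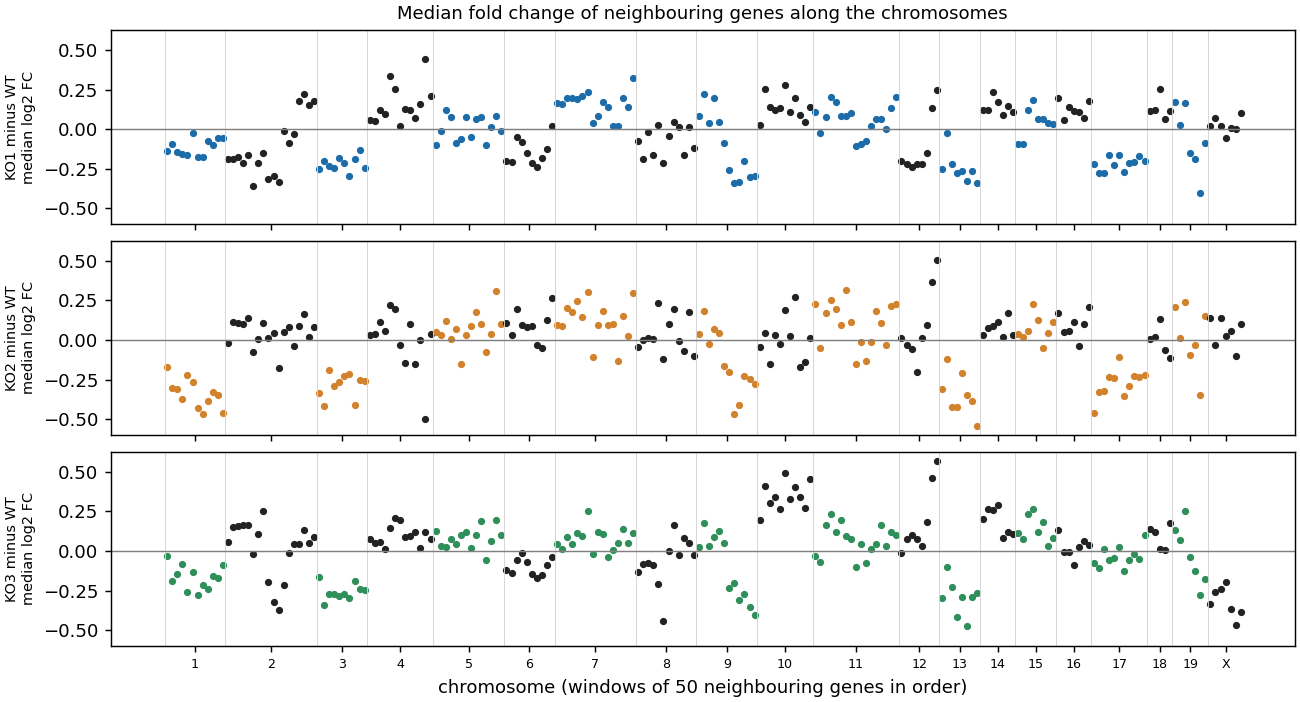
Median log2 fold change against WT (y axis) of windows of 50 neighbouring genes along chromosomes 1 to 19 and X (x axis, genes in order) in KO1, KO2 and KO3. The window of chromosome 12 that ends at 113137206 lies at 0.25, 0.51 and 0.57.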

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

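The test against shuffled gene orders was chosen after its result was seen, and the removal of GC and length trends and of the neighbours' median were added after the data were seen. Crls1 RNA differed between clones, at 0.727 for KO2 minus KO1 and 0.852 for KO3 minus KO1 on the log2 scale (limma, adjusted p = 3.18e-05 and 8.74e-06).

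Lower cholesterol synthesis genes in all 3 clones were weighed first. A trend on GC content or transcript length and a shift of whole chromosome regions both fail as the whole cause, since the least negative list median over the clones was -0.652 with the first removed and -0.581 with the second. WT replicate 1 alone fails as well, since the median was -0.660 without it and the list stayed called. The clones' history of editing, sorting and outgrowth, culture density and a response to lower Crls1 stay open, since the labels name no sorted clone with intact Crls1. An effect of Crls1 loss on sterol-regulated genes is thus only a hypothesis, and all 3 calls ended with an estimated correlation between genes (adjusted p = 0.397, 0.229 and 0.224).

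Integrated stress response genes were high in KO3 and low in KO2, with list medians 1.56 apart. The gap was 1.59 with GC and length trends removed and 1.33 with the neighbours' median subtracted, which argues against both as the whole cause. Opposite directions in lines that share the target, with Crls1 RNA differing by 0.12 between them (limma adjusted p = 0.253), leave clonal variation and culture state among the open explanations. The RNA level does not show whether the 2 lines keep the same amount of working enzyme. None of these was tested. The labels give 1 medium for all samples but not the density or time of harvest.

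Neighbouring genes moved together in every clone. The smallest ratio, over the clones, of the SD of window medians to the highest SD of 200 shuffled orders was 1.84, and it was 1.83 with GC and length trends removed, so neither random placement nor such a trend accounts for it. Differences in chromosome copy number between the clones and the WT cells may be the source, a hypothesis that DNA data would test and that stays open here. Regulation of whole domains stays open too.

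Further lists differed between clones in camera's own test of the difference, given as medians of the gene-by-gene log2 differences. For KO2 minus KO1 these were the integrated stress response (-0.739), cholesterol synthesis (-0.324), fatty acid oxidation (0.334), hypoxia targets (-0.371), cell cycle (-0.484), cytosolic ribosomal proteins (0.148) and contractile and YAP targets (-0.265). For KO3 minus KO1, the mitochondrial lists were ribosomal proteins (0.121), translation factors (0.206), mitochondrial DNA expression (0.213) and the unfolded protein response (0.203). Others were the integrated stress response (0.734), endoplasmic reticulum chaperones (-0.355), cholesterol synthesis (-0.428), glycolysis (0.230), NRF2 targets (0.474), cytosolic ribosomal proteins (0.290) and interferon-stimulated genes (-0.614). Extracellular matrix (-0.369) and markers of adipocytes (0.341), myogenic cells (-1.77), skeletal lineages (-0.838) and macrophages (-0.823) differed as well. For KO3 minus KO2 they were mitochondrial translation factors (0.143), mitochondrial DNA expression (0.320), the mitochondrial unfolded protein response (0.290), the integrated stress response (1.32), NRF2 targets (0.395), cell cycle (0.530), cytosolic ribosomal proteins (0.164), interferon-stimulated genes (-0.858) and adipocyte markers (0.856). With an estimated correlation only the interferon differences held (adjusted p = 0.0101 and 0.0124).

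The libraries were also regrouped. Of 100 groupings, the real one included, 1 gave as many genes changed alike in all 3 clones (3953, highest other 2176), which excludes, for that count, a chance assignment of libraries to groups. Since libraries of a line may be technical replicates, it does not bear on chance differences between lines. For each single comparison 10 splits of 6 libraries exist, too few for a share under 0.05. The real counts were 7878 genes in KO1, 9105 in KO2 and 8151 in KO3 (highest other 0, 0 and 1), and 6695, 6579 and 8008 between KO1 and KO2, KO1 and KO3, and KO2 and KO3 (highest other 1 each), so 1 of 10 splits, the real one, gave as many. For lists, the real counts were 4, 10 and 13 in KO1, KO2 and KO3, the highest other counts 10, 10 and 12, and the numbers of splits with as many 10, 5 and 1. The numbers of lists called in KO1 and KO2 are thus no larger than splits that mix WT and clone libraries gave. Mixed splits still keep part of any difference between WT and the clone, so they are not a reference without a difference. The comparison therefore cannot decide whether such a number reflects a difference between the lines.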

How the results depend on the processing

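The tests with edgeR and DESeq2, the sums with nuclear copies, the GC and length correction and the subtraction of the neighbours' median were chosen after the data were seen. Of 29 alternatives, 24 were planned. Crls1 was called in every clone under each alternative that gave it a value, with ranges of -2.11 to -1.89 in KO1, -1.31 to -1.15 in KO2 and -1.16 to -0.853 in KO3. Counts of called genes stayed within 1.5 times, at 6676 to 8461 in KO1, 7955 to 9457 in KO2, 7004 to 8734 in KO3 and 3350 to 4290 for genes changed alike in all 3. EdgeR on the recovered reads called 7879, 9124 and 8119 genes and DESeq2 7952, 9156 and 8242. Counts of called lists moved more. With no filter they were 9 in KO1 and 17 in KO2, with quantile normalization 7 and 17, with the neighbours' median subtracted 7 in KO1, and with an estimated correlation 0 in KO1, 0 in KO2 and 0 in KO3. Leaving out single libraries gave 4 to 7 lists in KO1 (7 without WT replicate 1), 9 to 15 in KO2 and 10 to 14 in KO3. Among uncalled lists in KO2, leaving out 1 library gave calls of mitochondrial dynamics and mitophagy (adjusted p = 0.0458 without WT replicate 2), NRF2 targets (0.0318 and 0.0279 without WT replicates 2 and 3), cytosolic ribosomal proteins (0.0208 and 0.0312, likewise), and, without WT replicate 1, endoplasmic reticulum chaperones (0.0414), adipocyte markers (0.0437) and import and cristae (0.0495). In KO1 it gave calls of adipocyte markers (0.0449) and cytosolic ribosomal proteins (median -0.0988, 0.0179) without WT replicate 1 and of fatty acid synthesis without WT replicate 3 (0.0442), and in KO3 of apoptosis regulators without WT replicate 3 (0.0478). Of the 27 called list results, 20 kept their call under the 24 settings other than the estimated correlation. With that setting, calls were lost even where the estimate lay below the preset 0.01. Examples were interferon-stimulated genes in KO1 (-0.0128) and hypoxia targets (-0.00038) and fibroblast markers (-0.0495) in KO2. For these lists a higher correlation between their genes was not the reason.

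The 505 named gene results gave 13089 values under the alternatives, of which 16 had the opposite sign where the reported or the alternative value was called, 95 lost a call, 61 gained one and 12917 did none of these. Most of these genes were picked from the same data for large changes or small adjusted p, and 454 of the 505 results were called. Their stability therefore does not stand for that of all genes. Mt-Co1 lost its call with quantile normalization by construction, as it ranked 1 in every library, and for the other changes the cause was not tested. Quantile normalization gave mt-Cytb 0.0846 in KO2, mt-Nd2 0.303 in KO1 and 0.371 in KO3, mt-Nd4l_4 0.0581 in KO1 and mt-Nd5 0.400 in KO1 and 0.379 in KO2. Leaving out single libraries moved mt-Rnr1 between -0.510 and 0.483 in KO1 and between -0.579 and 0.413 in KO2, the lowest without WT replicate 2. With the neighbours' median subtracted, Atp5f1 was at 0.0335 in KO2, Pgs1 at -0.00109 and Polrmt at -0.0262 in KO1 and Atp5a1 at -0.0130 in KO3. With GC and length trends removed, Polrmt was at -0.0531 and Hsd17b10 at -0.149 in KO2. Summing with the nuclear copy put mt-Nd3 at -0.273 in KO1 and -0.224 in KO2.

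The replicate numbers were not treated as pairs. Samples of the same number deviated from their group means with correlations of -0.221 to 0.123 (median -0.00426 over 18 pairs), and 3 libraries were closest to their own number. With the replicate number as a block, 7521, 8862 and 7865 genes were called in KO1, KO2 and KO3 and 3788 alike in all 3, and the list counts were 4, 10 and 12, the mitochondrial unfolded protein response in KO3 being the list call lost (adjusted p = 0.0562). Depth limits what can be said of genes with few reads, whose folds are given as bounds or counting intervals.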

Other observations

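The values in this part come from tests and alternatives fixed beforehand, with an exception. The result with the neighbours' median subtracted used a setting added after the data were seen. The choice of which lists and alternatives to describe was also made after the results were seen. Extracellular matrix genes moved strongly in both directions. Of 47, 21 rose and 18 fell in KO1, 18 rose and 21 fell in KO2, and 15 rose and 24 fell in KO3, of which 10 rose and 12 fell in every clone (camera adjusted p = 0.790, 0.919 and 0.169). Adjusted over the list alone, the counts were 21 and 18, 19 and 22, and 15 and 25. The fibrillar collagen Col3a1 went from 148 normalized counts in WT to 7939 in KO1, 884 in KO2 and 3664 in KO3, while Col8a1, a short-chain collagen, had log2 fold changes of -2.42, -3.02 and -2.22 and the matricellular protein Thbs1 of -2.35, -2.67 and -4.20. Immediate early genes, which respond within minutes to growth factors, divided as well, with 12 that rose and 8 that fell of 25 in KO1, 12 and 8 in KO2, and 9 and 9 in KO3, the same adjusted over the list alone (camera adjusted p = 0.201, 0.507 and 0.354). Egr1 rose by 1.79, 1.75 and 1.55, and the phosphatase gene Dusp1 fell by 2.50, 2.26 and 2.03. Of 13 epithelial markers, 5 passed the filter on low values. Of these, 4, 4 and 3 rose and 1 fell in KO1, KO2 and KO3 (camera adjusted p = 0.169, 0.137 and 0.327; 4, 4 and 3 up and 1, 1 and 2 down adjusted over the list alone). The cadherin Cdh1 went from 17.8 to 350, 185 and 307 normalized counts and Krt14 rose by 2.34, 2.86 and 2.83, whereas Krt8 was at -3.91, -3.04 and -4.17.

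Ppargc1a, a coactivator of mitochondrial gene expression, rose from 79.3 to 669, 530 and 865 normalized counts in KO1, KO2 and KO3, though its list, mitochondrial DNA expression and RNA processing, did not pass the test. There 5 rose and 11 fell of 36 in KO1, 5 and 16 in KO2, and 13 and 3 in KO3 (camera adjusted p = 0.201, 0.0823 and 0.327; 4 and 10, 5 and 16, and 13 and 3 adjusted over the list alone). In KO2 it was called lower with no filter (adjusted p = 0.0189), with quantile normalization (0.0383) and with the neighbours' median subtracted (0.0453). Pink1, a kinase that marks damaged mitochondria for mitophagy, rose by 1.93, 2.58 and 1.82 and the autophagy receptor Sqstm1 by 0.64, 0.55 and 1.38. In the list of mitochondrial dynamics and mitophagy 7 rose and 3 fell of 21 in KO1, 11 and 3 in KO2, and 9 and 4 in KO3 (camera adjusted p = 0.252, 0.0553 and 0.192; 7 and 3, 11 and 4, and 10 and 5 adjusted over the list alone). Of 26 phospholipid synthesis genes, 6 rose and 10 fell in KO1, 8 and 10 in KO2, and 6 and 12 in KO3 (camera adjusted p = 0.374, 0.813 and 0.181, the same counts adjusted over the list alone), with Agpat5, an acyltransferase, at -0.44, -0.76 and -0.51 and Lpcat1, which remodels phosphatidylcholine, at -1.07, -1.44 and -1.26. Of 22 glycolysis genes, 5 rose and 9 fell in KO1, 7 and 11 in KO2, and 7 and 7 in KO3 (camera adjusted p = 0.258, 0.361 and 0.980; 12 fell in KO2 adjusted over the list alone), and lactate dehydrogenase Ldha fell by 0.47, 0.79 and 0.53. Of 19 p53 targets, 7 rose and 2 fell in KO1, 7 and 6 in KO2, and 9 and 5 in KO3 (camera adjusted p = 0.258, 0.811 and 0.387; 6 fell in KO3 adjusted over the list alone), with Polk, a translesion DNA polymerase, at -0.93, -0.84 and -0.90. Of 14 nuclear noncoding RNAs, 2 rose and 6 fell in KO1, 3 and 9 in KO2, and 5 and 5 in KO3 (camera adjusted p = 0.374, 0.421 and 0.897; 7 fell in KO1 adjusted over the list alone).

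The remaining lists were not called in any clone in the main test. With no filter, histone genes were called lower in KO1 (adjusted p = 0.0155) and KO3 (0.0106), and apoptosis regulators in KO3 (0.0163). With quantile normalization, lysosome and autophagy genes were called higher in KO1 (0.0193) and KO2 (0.0383). Genes that rose and fell in KO1, KO2 and KO3 numbered 5 and 10, 6 and 15, and 10 and 5 of 40 for mitochondrial import and cristae (camera adjusted p = 0.568, 0.401 and 0.387), and 6 and 6, 6 and 4, and 7 and 3 of 20 for the TCA cycle (0.790, 0.813 and 0.248). For histone genes they were 0 and 5, 0 and 3, and 2 and 3 of 12 (0.258, 0.674 and 0.549), and for inflammatory cytokines 10 and 4, 4 and 5, and 8 and 6 of 19 (0.201, 0.942 and 0.810). Apoptosis regulators gave 3 and 8, 6 and 5, and 2 and 11 of 17 (0.256, 0.813 and 0.0678), and lysosome and autophagy genes 12 and 4, 10 and 6, and 10 and 6 of 29 (0.201, 0.401 and 0.604). Among cell type markers the counts were 3 and 2, 2 and 2, and 1 and 2 of 7 for myogenic cells (0.642, 0.755 and 0.405), 2 and 3, 1 and 4, and 1 and 5 of 7 for skeletal lineages (0.790, 0.507 and 0.0806), 4 and 1, 2 and 2, and 2 and 2 of 7 for endothelium (0.702, 0.663 and 0.795), and 3 and 2, 0 and 2, and 0 and 3 of 9 for macrophages (0.594, 0.612 and 0.269). Adjusted over the list alone, the counts were 4 and 9, 6 and 15, and 10 and 4 for import and cristae, 5 and 4 in KO2 for the TCA cycle, 0 and 2 in KO2 for histones, and 11 and 4 in KO1 and 8 and 7 in KO3 for cytokines. They were 5 and 9, 8 and 5, and 3 and 11 for apoptosis regulators, 13 and 4 in KO1 and 10 and 7 in KO3 for lysosome genes, and 3 and 2 in KO2 and 2 and 3 in KO3 for endothelium, with no change for the others.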
